A study of Mus musculus with 6 samples.

How the data were processed

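The series measured messenger RNA in wild-type mouse bone marrow-derived macrophages, primary macrophages differentiated in culture from bone marrow. Per the labels, the cells were incubated for 24 h in equal parts of fresh medium and medium conditioned by alveolar macrophages, the resident macrophages of the lung air spaces. The alveolar macrophages came from mice 8 to 12 weeks old, were separated by HTR2C, the serotonin receptor 2C, and had conditioned the medium for 48 h, per the series' design text. There were 3 libraries with medium from HTR2C-negative cells (N1 to N3 below) and 3 with medium from HTR2C-positive cells (P1 to P3), each placed in its group by its label. The labels number the samples but do not say whether the numbers stand for separate cultures, animals or batches of medium, so p-values measure the spread between these samples, which may be technical. No library without conditioned medium was analysed here.

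Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the VAHTS Universal V6 RNA-seq kit. The submitters' processing notes name fastp, HISAT2, StringTie and edgeR and the mouse genome build GRCm39, without versions. The counting settings, including the use of strand and of reads that map to several places, and the annotation release are not given in the sources used here. The deposited table holds 21959 Ensembl genes, each with a read count and an FPKM value per library, GRCm39 coordinates, a length and annotation terms. The counts, per the file headers, are whole numbers of reads per gene with no normalization. The deposited FPKM values equal the count divided by the gene length and by the library's total count, with a largest relative difference of 3.80e-07, so they carry no scaling beyond the total. Of the gene IDs, 21851 were found in the GENCODE M21 annotation, where 21723 are protein-coding. That annotation is on another build and was used only for transcript GC content, never for coordinates. The table itself gives no biotype.

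Total counts per library ranged from 12843971 to 16031723, and 12147 to 13179 genes had at least 1 count. A count of 0 allows up to 3 counts, which is 0.187 to 0.234 CPM depending on the library. That floor covers counting error alone, and the reads carry no molecular identifiers.

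Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing edgeR's filterByExpr were kept (10177), libraries were scaled with TMM factors, and the groups were compared with the robust quasi-likelihood F test without further covariates. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. Log2 fold changes are HTR2C-positive minus HTR2C-negative medium, with the standard error (SE) from the same fit. CPM values are TMM-scaled, given as mean ± SD over 3 libraries. Of the 45 gene lists fixed before the data were examined, 42 had at least 5 tested members. They were compared with all other genes by camera in edgeR with a preset correlation of 0.01, and again with an estimated correlation. The estimate also lowers the degrees of freedom of camera's test to the few residual ones of the 6 libraries. A call lost with it is thus not necessarily lost to correlation between genes. Fry was run beside camera and asks another question, whether a list's own genes move on balance one way, without comparison to other genes. Annotation terms of the table with 10 to 300 tested genes (3237 terms) were tested with camera in the same way. Camera's adjusted p-values are over the lists or over the terms.

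The tests were tried on counts simulated from the means, spreads and library sizes of these 6 libraries, with 200 of 10177 genes changed, over 5 simulations. The changed genes were in equal parts 1.5-, 2-, 3- and 4-fold. The larger changes ease the adjusted threshold for the smaller ones, so with fewer strong changes the rates below may be lower. The fit found 9.0% of genes changed 1.5-fold, 55.6% of those changed 2-fold, 79.2% of those changed 3-fold and 87.0% of those changed 4-fold, and called 0.1% of unchanged genes. Camera called a set raised 1.4-fold in 5 of 5 simulations and 0 of 100 unchanged sets. Genes were simulated independently and without the trend with GC content described at the end. These rates therefore do not cover lists of genes that vary together or follow that trend.

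The genes to name were fixed as a rule before the data were examined. The rule takes the genes with the largest changes past the threshold or, if none passes, the 10 with the smallest p among genes with a mean of at least 2 CPM, no overlap between the groups and an ordinary symbol. It adds up to 4 members with the smallest p of each list described, and Htr2c, Csf1r, Adgre1 and Itgam. Of the genes so taken, 2 are not reported here. Alternatives planned in advance were RLE factors, total counts alone, no count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1 in one group, a pseudocount of 0.1 or no filter there, and leaving out each library. A fit to protein-coding genes alone was planned where the table gives a biotype and was not run. Added after seeing the data were a threshold of 0.1, the count of genes with an unadjusted p under 0.05, leaving out N2 and P1 together, and a correction for GC content and length. The correction fitted each library's deviation in log2 CPM with natural splines of GC content and log length (5 degrees of freedom each) and entered the fit as edgeR offsets, with and without the replicate block. It was fitted without regard to group, so it also removes any effect of the medium that follows GC content or length. A call lost with it is thus not shown to be an artefact. GC content was that of one GENCODE transcript per gene and was known for 10162 of the tested genes.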

Results

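The comparison asked how the transcriptome of bone marrow-derived macrophages differs after 24 h in medium conditioned by HTR2C-positive alveolar macrophages, set against medium from HTR2C-negative ones. The title of the series describes the effect of the former as reprogramming. RNA-seq read counts were given for 3 libraries per group. N1, N2 and N3 (HTR2C-negative medium) held 12843971, 13745685 and 16031723 counts, and P1, P2 and P3 (HTR2C-positive medium) held 15559219, 15728400 and 15545190.

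Macrophage and inflammatory transcripts were abundant in both groups. After the actin gene Actb (7.03% to 13.5% of counts per library) and the syndecan gene Sdc4 (3.46% to 4.27%) came Lyz2, which encodes lysozyme, with a mean share of 1.74%, the ferritin gene Fth1 with 1.33%, the peroxiredoxin gene Prdx1 with 1.12% and the chemokine gene Ccl5 with 1.06%. The interferon-induced antiviral gene Rsad2 held a mean 0.808%, the acute-phase gene Saa3 0.784%, Ifit1 0.498% and Il1b 0.405%. The macrophage genes Adgre1, a surface marker of mature macrophages, and Itgam, an integrin gene of myeloid cells, were at 1287 ± 353 and 170 ± 26.4 CPM with HTR2C-negative medium and 1221 ± 541 and 184 ± 41.3 CPM with HTR2C-positive medium (SD, n = 3), with log2 fold changes of -0.08 (SE 0.27) and 0.11 (SE 0.19). Csf1r, the receptor of the macrophage growth factor CSF1, was at 106 ± 21.5 and 164 ± 31.1 CPM, a log2 fold change of 0.63 (SE 0.19, adjusted p = 0.141), and 0.35 with the trend described at the end removed. Htr2c itself (chromosome X, 145745509 to 145980273, GRCm39) had 0 counts in each of the 6 libraries of the receiving cells, which allows up to 0.187 to 0.234 CPM.

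Between the media, transcripts of cytosolic ribosomal proteins and of NF-kB target and feedback genes were higher as sets with HTR2C-positive medium, and so were the fixed markers of neutrophils, by camera with its preset correlation. With an estimated correlation all 3 calls were lost (adjusted p = 0.798, 0.555 and 0.798), and with the GC and length trend removed the NF-kB and neutrophil calls were lost as well (adjusted p = 0.160 and 0.0580). The estimated correlation of the NF-kB list was -0.001, under the preset, so its loss there came with the fewer degrees of freedom. That of the ribosomal and neutrophil lists was 0.45 and 0.124, above the preset, so for these correlation between genes can count as well. Slopes of the GC trend separated the groups, so removing the trend can also take out an effect of the medium. Single interferon-induced GTPase genes had lower values. The differences of single genes were mostly near or under 2-fold and none passed the correction over all genes. With edgeR, 0 of 10177 genes had an adjusted p under 0.05, the lowest being 0.0616, while 1690 had an unadjusted p under 0.05, 804 higher and 886 lower with HTR2C-positive medium. DESeq2 called 384 genes, 114 higher and 270 lower, and limma-voom called 0. Without library N2 edgeR called 206 genes, without library P1 186, and without both 1107, so the count depends on these libraries. N2 and P1 were the most alike of all pairs of libraries (r = 0.980), though from different groups. Leaving them out thus tends to widen the difference between groups, so the 1107 cannot be read as changes these libraries hide. In 2274 genes (22.3%) the groups did not overlap, where the average over all splits 3 against 3 is 10%. Genes that vary together can move this share far from the average in a single split. The shares of the other splits were not computed, so the 22.3% cannot be called more than chance gives. Fold changes also followed GC content across genes, as described at the end.

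The 9 genes with the smallest p described here all failed the correction at an adjusted p of 0.0616, with no overlap between the groups, which the naming rule required. Of these, 3 had higher values with HTR2C-positive medium. Cebpd (ENSMUSG00000071637, chromosome 16, 15705150 to 15708895), a C/EBP-family transcription factor gene induced in inflammation, was at 7.50 ± 1.42 CPM with HTR2C-negative and 18.3 ± 0.443 CPM with HTR2C-positive medium, a log2 fold change of 1.29 (SE 0.21). C1qc (ENSMUSG00000036896, chromosome 4, 136617115 to 136620376), which encodes a chain of complement C1q, was at 81.2 ± 16.1 and 169 ± 23.5 CPM (1.05, SE 0.18). Lrp10 (ENSMUSG00000022175, chromosome 14, 54701594 to 54708954) was at 21.4 ± 2.35 and 43.2 ± 5.95 CPM (1.01, SE 0.18).

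The other 6 had lower values with HTR2C-positive medium. Gbp7 (ENSMUSG00000040253, chromosome 3, 142236103 to 142255910), a guanylate-binding protein gene induced by interferon, was at 2681 ± 586 CPM with HTR2C-negative and 1248 ± 84.2 CPM with HTR2C-positive medium (log2 fold change -1.10, SE 0.18). Cebpg (ENSMUSG00000056216, chromosome 7, 34745847 to 34755998), a C/EBP-family gene that acts with ATF4, was at 57.3 ± 7.32 and 28.7 ± 3.71 CPM (-0.996, SE 0.17). Lrrc58 (ENSMUSG00000034158, chromosome 16, 37688751 to 37709220) was at 918 ± 285 and 387 ± 52.6 CPM (-1.25, SE 0.21). Zbtb38 (ENSMUSG00000040433, chromosome 9, 96564823 to 96634884), Zfp386 (ENSMUSG00000042063, chromosome 12, 116011344 to 116026980) and Sinhcaf (ENSMUSG00000039985, chromosome 6, 148822533 to 148847965), which encode nuclear proteins, had log2 fold changes of -0.98 (SE 0.15), -1.01 (SE 0.17) and -1.08 (SE 0.19). After removal of each library's trend with GC content and length, these genes kept their signs, with log2 fold changes of 0.54 for Lrp10, 0.71 for C1qc, 1.19 for Cebpd and -0.73 (Zfp386) to -1.02 (Lrrc58) for the rest.

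**Figure D1:**
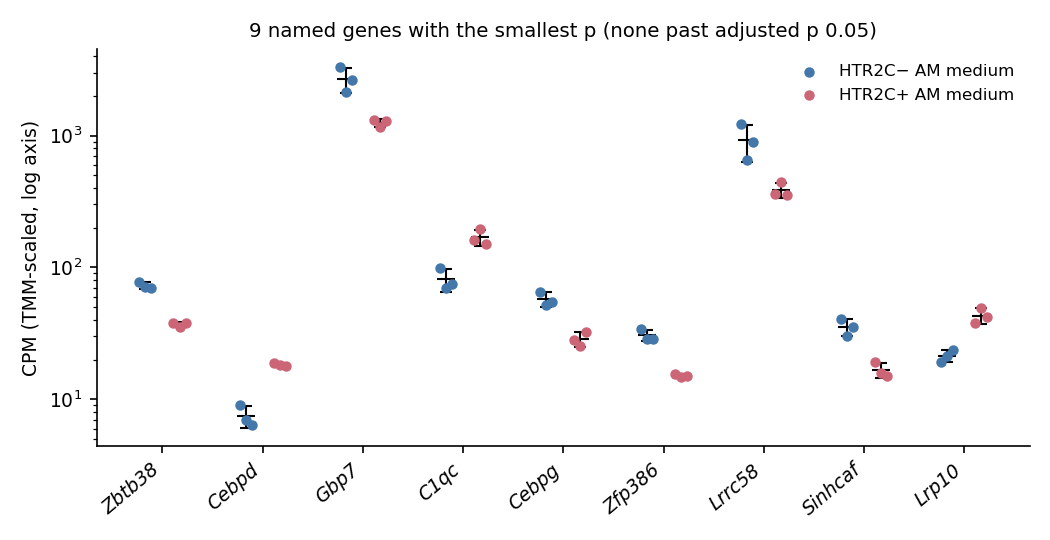
TMM-scaled CPM (log axis) of 9 genes with the smallest p in the 3 libraries with HTR2C-negative medium (blue) and the 3 with HTR2C-positive medium (red). Points are libraries and black bars are mean ± SD. The groups do not overlap in any of these genes, as the rule that chose them required. Cebpd, C1qc and Lrp10 are higher with HTR2C-positive medium, and none of the 9 genes has an adjusted p under 0.05.

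Interferon-induced genes gave a mixed picture. Of 31 tested genes of the interferon gamma response and guanylate-binding protein list, 7 were lower and 2 higher with HTR2C-positive medium at an unadjusted p under 0.05. Adjusted over the list alone, 7 were lower and 1 higher, against 0 over all genes tested. Beside Gbp7, the GTPase genes Tgtp2 (3358 ± 718 and 1923 ± 157 CPM, log2 fold change -0.80), Tgtp1 (-0.65) and Iigp1 (-0.66) had the smallest p. Tgtp1 and Tgtp2 are close paralogs, and the guanylate-binding and Ifi200 genes belong to families of similar sequence, so their counts are uncertain to the extent that reads were split between copies. The median of the list was -0.21, its mean -0.09, and camera did not set it apart from other genes (adjusted p = 0.140). Without library P1 that p was 0.0161, and without N2 and P1 0.00379, though the median was then -0.05, and it was -0.06 when libraries were scaled to total counts alone. Of 40 type I interferon-stimulated genes, 8 were lower and 0 higher at an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. Ifi209 was at 3595 ± 663 and 1971 ± 85.4 CPM (-0.87, SE 0.17), and Ifit2 (-0.68), Ifit3 (-0.47) and Ifi205 (-0.50) also had separated groups. The list median was -0.08 (camera adjusted p = 0.202) and became 0.06 when libraries were scaled to total counts alone. The median GC content of these lists was 46.8% and 47.5%, on the side where fold changes were lower. With the GC and length trend removed, the medians were -0.14 and -0.05 (adjusted p = 0.310 and 0.508), and the log2 fold changes -0.53 for Tgtp2, -0.40 for Tgtp1, -0.35 for Iigp1, -0.52 for Ifi209, -0.41 for Ifit2, -0.31 for Ifit3 and -0.17 for Ifi205.

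The list of NF-kB feedback and target genes was higher as a set with HTR2C-positive medium. Of its 29 tested genes, 21 had a positive fold change, with a median log2 fold change of 0.24, and 12 were higher and 2 lower at an unadjusted p under 0.05. Adjusted over the list alone, 8 were higher and 0 lower. Camera gave an adjusted p of 0.00369 with its preset correlation. With an estimated correlation, which was -0.001, the adjusted p was 0.555, on fewer degrees of freedom. Relb, the non-canonical NF-kB subunit, was at 12.0 ± 3.03 and 24.5 ± 5.02 CPM (log2 fold change 1.03, SE 0.23). Nfkb2, its partner, was at 109 ± 9.95 and 174 ± 16.4 CPM (0.68, SE 0.15). The feedback gene Zc3h12a had a log2 fold change of 0.64 and Bcl3, an I-kappa-B family gene, one of 0.70. Mean levels of the list were 7.88 to 7.99 log2 CPM with HTR2C-negative and 8.12 to 8.24 with HTR2C-positive medium. These genes had a median GC content of 53.6%, and with the GC and length trend removed the median was 0.15 and the adjusted p 0.160, with log2 fold changes of 0.51 for Relb, 0.18 for Nfkb2 (unadjusted p = 0.257), 0.29 for Zc3h12a (0.163) and 0.21 for Bcl3 (0.287).

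Cytokine and cytotoxic lists did not pass camera's threshold. Of 22 pro-inflammatory cytokines and M1-type markers, 4 were higher and 3 lower at an unadjusted p under 0.05, 0 when adjusted over the list alone, with a median of 0.05 (-0.03 without N2 and P1, camera adjusted p = 0.908). Marcksl1 had a log2 fold change of 0.54, the cytokine gene Il6 one of -0.56 (602 ± 122 and 408 ± 79.5 CPM), Cd38 -0.48 and the costimulatory gene Cd86 -0.58. Of 18 tumoricidal and cytotoxic effectors, 2 were higher and 1 lower at an unadjusted p under 0.05 and 0 passed adjusted over the list alone (median -0.03, 0.12 scaled to total counts and -0.14 without N2 and P1, camera adjusted p = 0.965). Tnf was at 277 ± 67.0 and 476 ± 272 CPM (0.78, SE 0.31, and 0.22 without library P1), with overlapping groups, and the inducible nitric oxide synthase gene Nos2 at 75.5 ± 20.4 and 100 ± 20.9 CPM (0.41). The NADPH oxidase genes Ncf1 and Cybb had log2 fold changes of 0.57 and -0.49. Of 24 chemokine genes, 19 had a positive fold change (median 0.19, and 0.09 without library P2, adjusted p = 0.910), with 1 higher and 1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone and a camera adjusted p of 0.348, which became 0.00261 (median 0.20) with the GC and length trend removed, or 0.753 with an estimated correlation in addition. Ccl22 was at 14.6 ± 0.425 and 21.9 ± 5.22 CPM (0.59), Cxcl10 at 1187 ± 71.3 and 1452 ± 234 CPM (0.29, and 0.17 without P1) and Cxcl5 at 50.5 ± 5.20 and 37.2 ± 2.23 CPM (-0.44). The log2 fold changes became -0.15 for Il6 (unadjusted p = 0.395), -0.19 for Cd38, -0.32 for Cd86, 0.18 for Marcksl1, 0.74 for Tnf, 0.17 for Nos2, 0.37 for Ncf1, -0.26 for Cybb, 0.60 for Ccl22, 0.35 for Cxcl10 and -0.002 for Cxcl5 once the GC and length trend was removed.

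Markers fixed for neutrophils were higher as a set with HTR2C-positive medium. Of 12 tested, 11 had a positive fold change (median 0.50), 4 were higher and 1 lower at an unadjusted p under 0.05, and 3 were higher and 1 lower when adjusted over the list alone. Camera gave an adjusted p of 0.0245. With an estimated correlation, which was 0.124, the adjusted p was 0.798. Lcn2, the lipocalin gene that inflamed macrophages also express, was at 96.0 ± 17.8 and 180 ± 52.9 CPM (0.90, SE 0.22), the receptor gene Csf3r at 93.8 ± 12.8 and 129 ± 18.9 CPM (0.46), the antimicrobial peptide gene Camp at 13.3 ± 0.680 and 19.2 ± 2.25 CPM (0.53) and the collagenase gene Mmp8 at 51.6 ± 5.79 and 36.9 ± 5.51 CPM (-0.48). The list mean was 4.12, 4.50 and 4.16 log2 CPM in N1, N2 and N3 and 4.85, 4.52 and 4.69 in P1, P2 and P3. With the GC and length trend removed, its median was 0.27 and the adjusted p 0.0580, and the log2 fold changes were 0.75 for Lcn2, 0.22 for Csf3r, 0.24 for Camp and -0.18 for Mmp8.

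Complement and phagocytosis genes included several with higher values. Of 14 complement genes, 4 were higher and 1 lower at an unadjusted p under 0.05, with 2 higher and 1 lower adjusted over the list alone (median 0.25, camera adjusted p = 0.325). The other C1q chain genes C1qb (390 ± 115 and 641 ± 187 CPM, log2 fold change 0.71, and 0.47 without P1) and C1qa (73.6 ± 27.7 and 130 ± 62.8 CPM, 0.82, and 0.37 without library P1, which was at 202 CPM) had overlapping groups, and Cr1l had a log2 fold change of -0.48. Of 32 phagocytosis and efferocytosis receptors, 9 were higher and 2 lower at an unadjusted p under 0.05, with 3 higher and 1 lower adjusted over the list alone (median 0.10, camera adjusted p = 0.270). Ptk2b was at 34.6 ± 4.09 and 57.5 ± 0.497 CPM (0.73), Mfge8, the bridge to apoptotic cells, at 17.7 ± 2.51 and 28.6 ± 6.09 CPM (0.69) and the scavenger receptor gene Cd36 at 742 ± 65.5 and 521 ± 48.0 CPM (-0.51). Removing the GC and length trend gave log2 fold changes of 0.36 for C1qb, 0.39 for C1qa, -0.30 for Cr1l, 0.46 for Ptk2b, 0.25 for Mfge8 (unadjusted p = 0.226) and -0.15 for Cd36 (0.298).

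Of 17 alternative activation markers, 5 were higher and 1 lower at an unadjusted p under 0.05, and 4 higher and 1 lower adjusted over the list alone (median 0.07, camera adjusted p = 0.484). Il4ra, the interleukin 4 receptor gene, was at 91.9 ± 18.0 and 152 ± 10.4 CPM (0.73, SE 0.17), Socs1 at 10.01 ± 2.36 and 24.3 ± 16.7 CPM (1.28, SE 0.38, and 0.57 without library P1), Tgm2 had a log2 fold change of 0.57 and Cd200r1 one of -0.52. Of 25 immunosuppressive and checkpoint genes, 4 were higher and 2 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (median 0.11, and 0.22 without N2 and P1, camera adjusted p = 0.639), among them Sirpa (0.52), Siglec1 (0.70), Nectin2 (0.88, and 0.49 without library P1) and Trem2 (0.44). Of 14 MHC class II presentation genes, 1 was higher (H2-Eb1, 0.37) and 1 lower (Cd86) at an unadjusted p under 0.05 and 0 passed adjusted over the list alone (median 0.11, and 0.01 without N2 and P1, camera adjusted p = 0.809). Of 24 alveolar macrophage identity genes, 1 was higher and 4 lower at an unadjusted p under 0.05 and 0 passed adjusted over the list alone (median -0.12 and, scaled to total counts, 0.03, camera adjusted p = 0.316). Among them, Cd200r4 (-0.52), the lipid exporter gene Abcg1 (-0.54, and -0.36 without P1) and Atp6v0d2 (-0.42) had the smallest p of those with lower values. After removal of the GC and length trend, the log2 fold changes were 0.38 for Il4ra, 0.82 for Socs1, 0.17 for Tgm2, -0.22 for Cd200r1, 0.24 for Sirpa, 0.30 for Siglec1, 0.44 for Nectin2, 0.02 for Trem2 (unadjusted p = 0.909), 0.35 for H2-Eb1, -0.13 for Cd200r4, -0.74 for Abcg1 and -0.09 for Atp6v0d2.

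Genes of sterol metabolism had mostly positive fold changes. Of 20 LXR target and cholesterol efflux genes, 15 had a positive fold change (median 0.33), 6 were higher and 1 lower at an unadjusted p under 0.05, and 5 were higher adjusted over the list alone (camera adjusted p = 0.140). Nr1h2, which encodes LXR beta, was at 17.4 ± 3.66 and 29.3 ± 8.19 CPM (log2 fold change 0.75), Srebf1 at 3.06 ± 0.368 and 5.82 ± 1.26 CPM (0.92), and Ucp2 and Pltp had log2 fold changes of 0.55 and 0.65. Of 24 cholesterol biosynthesis genes, 18 had a positive fold change (median 0.23, and 0.05 without N2 and P1), 3 were higher and 1 lower at an unadjusted p under 0.05 and 3 were higher adjusted over the list alone (camera adjusted p = 0.140, and 0.00895 without P3). Mvd, a mevalonate pathway enzyme gene, was at 2.09 ± 0.773 and 5.70 ± 1.201 CPM (1.45, SE 0.36) and Srebf2 at 15.8 ± 3.07 and 26.1 ± 6.0 CPM (0.72). The list mean was 4.24 log2 CPM in P1 and 3.58 to 3.79 in the other 5 libraries. Of 36 G2/M genes, whose list means lay between 0.97 and 1.53 log2 CPM, 26 had a negative fold change (median -0.27), 1 was higher (Aurkb) and 5 lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone (camera adjusted p = 0.219). Log2 fold changes free of the GC and length trend were 0.25 for Nr1h2 (unadjusted p = 0.182), 0.47 for Srebf1, 0.22 for Ucp2, 0.32 for Pltp, 1.06 for Mvd and 0.27 for Srebf2. The LXR list then had an adjusted p of 0.315 (median 0.24), and the cholesterol biosynthesis list one of 0.0421 (median 0.26), or 0.753 with an estimated correlation.

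Transcripts of cytosolic ribosomal proteins had the smallest p of the 42 lists by camera with its preset correlation. Of 74 tested, 71 had a positive fold change (median 0.36), 36 were higher and 0 lower at an unadjusted p under 0.05, and 21 were higher adjusted over the list alone. Camera gave an adjusted p of 1.80e-14. With an estimated correlation, which was 0.45, the adjusted p was 0.798. Rps18 was at 71.7 ± 8.42 and 117 ± 12.1 CPM (log2 fold change 0.70, SE 0.16), Rpl8 at 73.8 ± 6.30 and 116 ± 4.34 CPM (0.65), Rpl27a at 31.0 ± 3.33 and 50.6 ± 2.01 CPM (0.71) and Rpl19 at 60.8 ± 2.35 and 90.1 ± 11.9 CPM (0.57). Together they took 0.624%, 0.718% and 0.695% of counts in N1, N2 and N3 and 0.868%, 0.917% and 0.908% in P1, P2 and P3. Many ribosomal protein genes have processed pseudogenes of near-identical sequence, so their counts are uncertain to the extent that shared reads were dropped or split. With the GC and length trend removed the median was 0.31 and the adjusted p 2.68e-14, or 0.753 with an estimated correlation. The log2 fold changes were then 0.52 for Rps18, 0.27 for Rpl8, 0.80 for Rpl27a and 0.31 for Rpl19.

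**Figure D2:**
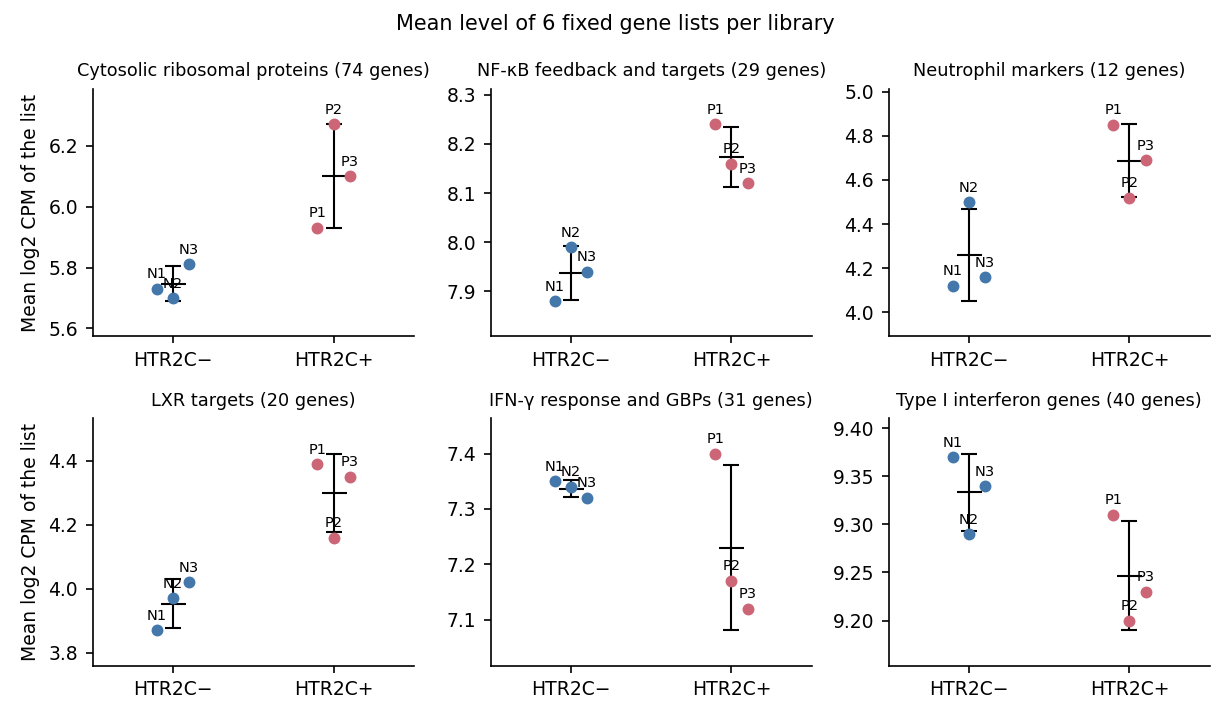
Mean log2 CPM of the tested members of 6 gene lists in each library, by medium. Points are libraries, labelled N1 to N3 and P1 to P3, and bars are mean ± SD over 3 libraries, and each panel has its own vertical scale. The groups do not overlap for ribosomal proteins (5.70 to 5.81 against 5.93 to 6.27), NF-kB genes, neutrophil markers (4.12 to 4.50 against 4.52 to 4.85) or LXR targets, and overlap for both interferon lists.

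Among annotation terms of the table, 13 of 3237 passed camera's threshold, 12 higher and 1 lower with HTR2C-positive medium, and 0 with an estimated correlation (adjusted p = 0.970 for each of the 13). On the few residual degrees of freedom, adjustment over 3237 terms leaves hardly any term able to pass. The 0 therefore cannot decide whether these terms stand apart. Cytosolic ribosome led (76 genes, median 0.36, adjusted p = 3.04e-12), and 9 further terms described ribosomes, translation or a coronavirus disease pathway, of whose 173 tested genes 74 were on the ribosomal protein list. The others were NIK/NF-kappaB signalling (12 genes, median 0.54, adjusted p = 0.00599) and lung morphogenesis (14 genes, median 0.56, adjusted p = 0.0300), both higher, and cellular response to interferon-beta (49 genes, median -0.26, adjusted p = 0.00267), lower. With the GC and length trend removed, 10 terms passed, all among the 13, and the interferon-beta, NIK/NF-kappaB and lung morphogenesis terms had adjusted p of 0.693, 0.457 and 0.457.

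The fold changes followed the GC content of the transcripts. Across 10162 genes, which are not independent replicates, Spearman's rho between log2 fold change and GC content was 0.56. In the quintile of genes with the lowest GC content (32.8% to 43.8%) the median log2 fold change was -0.28, with 5 genes higher and 509 lower at an unadjusted p under 0.05. In the quintile with the highest (55.1% to 68.7%) it was 0.41, with 497 higher and 8 lower. The slope of log2 CPM per 10 points of GC content, against the mean of the libraries, was -0.35, -0.04 and -0.22 in N1, N2 and N3 and 0.27, 0.18 and 0.15 in P1, P2 and P3. An exact two-sided permutation test of these slopes gave p = 0.1, the smallest that 3 against 3 libraries allow. With the trend removed, 961 genes had an unadjusted p under 0.05 in place of 1690, and 0 an adjusted p under 0.05.

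**Figure D3:**
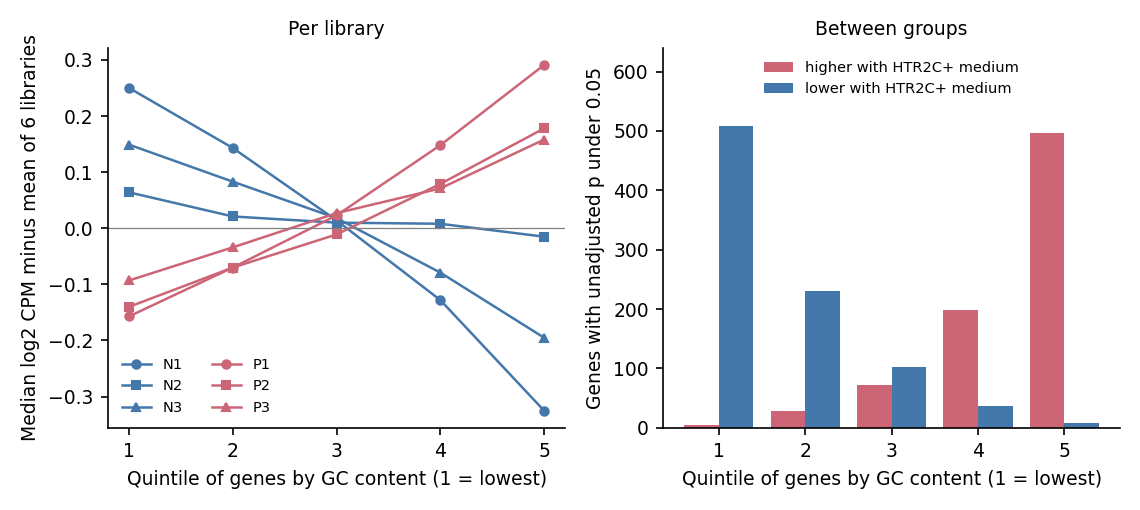
Genes in quintiles by GC content of their transcript, from 1 (lowest) to 5 (highest). Left, the median over genes of each library's log2 CPM minus the mean of the 6 libraries, with N libraries in blue and P libraries in red. Right, the number of genes with an unadjusted p under 0.05 that were higher (red) or lower (blue) with HTR2C-positive medium, 497 and 8 in the top quintile and 5 and 509 in the bottom one.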

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

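The threshold of 0.1, the count of genes with an unadjusted p under 0.05, the fits without N2 and P1 together and the GC and length correction were chosen after the result was seen. The 0 genes with an adjusted p under 0.05, in total, in each direction and among those changed at least 2-fold, stayed 0 with RLE factors, total counts alone, a filter of 1 CPM, limma-voom, limma on log2(FPKM + 1) or log2(FPKM + 0.1) and without its filter, the replicate block, the GC and length correction, and the correction with the block. Without a count filter edgeR called 422 genes, 206 higher and 216 lower with HTR2C-positive medium and 76 at least 2-fold. Of these 422, 421 were among the genes of the filtered fit, and the median degrees of freedom of the prior spread went from 9 to infinity. DESeq2 called 384 (114 higher, 270 lower, 42 at least 2-fold), with all 384 at an unadjusted p under 0.05 in edgeR. It gave an adjusted p to 6435 genes only. At a threshold of 0.1 edgeR called 167 (49 higher, 118 lower, 35 at least 2-fold). Leaving out 1 library gave 0 to 206 genes, 0 to 79 higher, 0 to 127 lower and 0 to 83 at least 2-fold. The calls came without N2 (206) or without P1 (186, of which 73 higher and 113 lower), and without both there were 1107 (455 higher, 652 lower, 183 at least 2-fold). The fits without N2, without P1, without a count filter and with DESeq2 shared 90 called genes, 22 higher and 68 lower. These fits use the same libraries, so a shared call is no independent support. Median GC content over the 4 fits was 56.7% to 57.3% for calls higher and 41.7% to 42.3% for calls lower. Of the 90, 87 had an unadjusted p under 0.05 with the GC and length trend removed. The cause of the other differences between settings was not tested.

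Genes with an unadjusted p under 0.05 numbered 847 (without N1) to 2097 (without N2) when 1 library was left out, 961 after the GC and length correction and 600 after the correction with the replicate block, against 1690, and lay within 1.5 times of it in the other settings. Scaling to total counts moved the median log2 fold change by 0.14 and the split of these genes from 804 higher and 886 lower to 1150 and 390. With the replicate number as a block 0 genes were called and 1175 had an unadjusted p under 0.05. Deviations from the group means correlated at -0.15, -0.23 and 0.05 between same-numbered libraries, so the numbers do not pair them, and the block changed no other call than 1 annotation term (12 in place of 13).

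The 3 fixed lists past camera's threshold became 0 with an estimated correlation, 3 to 5 when 1 library was left out (5 without P1) and 6 without N2 and P1. Fry's directional test, which does not compare a list with other genes, called 1 list, none of these 3 (phagocytosis and efferocytosis receptors, adjusted p = 0.0296), and 0 terms. Fry's mixed test asks whether a list's genes change in any direction. It gave adjusted p of 0.0359 (ribosomal), 0.0155 (NF-kB) and 0.0155 (neutrophil), and also passed lists that camera did not call, such as complement (0.012). By camera the ribosomal and NF-kB lists passed in each leave-one-out fit, as did the neutrophil list. Oxidative phosphorylation joined them without N1 (adjusted p = 0.0356), N3 (0.012) or P1 (0.000155), the interferon gamma list, lower, without P1 (0.0161), and cholesterol biosynthesis without P3 (0.00895). Without N2 and P1 together, oxidative phosphorylation (0.039) and both interferon lists, lower (0.00379 and 0.0495), passed as well. The 13 terms became 0 with an estimated correlation and 6 (without P2) to 21 (without P1) when 1 library was left out. After the GC and length correction 4 lists passed, with ribosomal proteins joined by chemokines (adjusted p = 0.00261), cholesterol biosynthesis (0.0421) and mitochondrially encoded transcripts (0.000265), all higher, and each of these 4 calls was lost with an estimated correlation (adjusted p = 0.753). The mitochondrial list had a low median GC content (37.4%) and an estimated correlation of 0.495 before the correction. Its median was then 0.04 (camera adjusted p = 0.965), so its call came with the correction. The median of the mitochondrial list changed sign without N2 (adjusted p = 0.621) and without P3 (0.398), in a range of 0.398 to 0.983 over the leave-one-out fits. Of 109 genes taken by the naming rule, 3 changed sign in a setting. Adgre1 went from -0.08 to 0.063 with total counts, 0.01 in each FPKM fit, 0.017 after the GC and length correction and -0.48 to 0.17 when 1 library was left out. Itgam went from 0.11 to -0.05 without P3, in a range of -0.05 to 0.29, and Csf2ra from 0.46 to -0.046 after the correction and -0.06 with the block added. At these depths and 3 libraries per group, changes of 1.5-fold are mostly missed.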

Other observations

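Chosen after the result was seen were the 3 tests of the GC trend, the removal of that trend from the ribosomal list and the splits for counts of genes.

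Further lists held genes with separated groups, though none passed over all genes. Of 7 serotonin receptor and metabolism genes tested, 2 were lower and 1 higher adjusted over the list alone (median 0.56, mean 0.04, camera adjusted p = 0.607), and the median was -0.04 without N2 and P1 and 0.17 with the GC and length trend removed. Slc18a2, the vesicular monoamine transporter gene, was at 56.4 ± 12.2 CPM with HTR2C-negative and 31.6 ± 3.10 CPM with HTR2C-positive medium (log2 fold change -0.84, SE 0.18), and Maoa, which encodes an enzyme that degrades serotonin, at 21.4 ± 3.90 and 12.4 ± 0.288 CPM (-0.79, SE 0.20). Of 31 unfolded protein response and ATF4 target genes, 5 were lower adjusted over the list alone (median 0.02, camera adjusted p = 0.467), among them Cebpg and the endoplasmic reticulum chaperone genes Hsp90b1 (191 ± 32.4 and 128 ± 2.04 CPM, -0.57), Creld2 (-0.63) and Dnajb9 (-0.77). Of 34 matrix and protease genes, 1 was higher and 2 lower adjusted over the list alone (median 0.13, camera adjusted p = 0.809). Mmp14, the membrane-bound metalloproteinase gene, was at 187 ± 29.9 and 348 ± 35.1 CPM (0.90, SE 0.16), Mmp12, the macrophage elastase gene, at 2311 ± 300 and 1496 ± 43.6 CPM (-0.63) and Mmp27 at 19.0 ± 4.90 and 8.76 ± 0.971 CPM (-1.11). The log2 fold changes became -0.61 for Slc18a2, -0.49 for Maoa, -0.36 for Hsp90b1, -0.85 for Creld2, -0.38 for Dnajb9, 0.63 for Mmp14, -0.34 for Mmp12 and -0.77 for Mmp27 once the GC and length trend was removed.

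Hk2, the hexokinase gene, was at 848 ± 209 and 433 ± 104 CPM (-0.97, SE 0.21) and was the 1 lower gene of 36 glycolysis and hypoxia genes adjusted over the list alone (median 0.12, camera adjusted p = 0.934). Igf1 (688 ± 118 and 436 ± 64.5 CPM, -0.66) and Itgb8 (-0.54) were the 2 lower of 26 growth factor and TGF-beta response genes (median 0.08, camera adjusted p = 0.908). Gsdme (-0.66) was the 1 lower of 21 inflammasome genes (median -0.02, 0.13 scaled to total counts, camera adjusted p = 0.488) and Tlr8 (-0.74) the 1 lower of 27 sensor genes (median -0.01, 0.11 scaled to total counts, camera adjusted p = 0.809). Ctsd, which encodes cathepsin D (119 ± 46.7 and 230 ± 44.6 CPM, 0.94), and Mitf (-0.83) passed among 47 lysosome genes (median 0.14, camera adjusted p = 0.295). Of 10 dendritic cell markers, Fscn1 was at 2.22 ± 0.505 and 5.37 ± 1.32 CPM (1.27, SE 0.34), with a list median of 0.19 and a camera adjusted p of 0.236. Removing the GC and length trend gave log2 fold changes of -1.11 for Hk2, -0.34 for Igf1, -0.26 for Itgb8, -0.41 for Gsdme, -0.41 for Tlr8, 0.69 for Ctsd, -0.62 for Mitf and 0.81 for Fscn1.

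The remaining lists did not pass camera's threshold. Median log2 fold changes and adjusted p were 0.16 and 0.117 for 70 nuclear oxidative phosphorylation genes, 0.17 and 0.140 for 17 metallothionein and iron genes, 0.20 and 0.202 for 19 glucocorticoid response genes, 0.07 and 0.295 for 22 MHC class I genes, 0.07 and 0.488 for 27 NRF2 targets, 0.09 and 0.965 for 30 lipid uptake genes, 0.13 (0.05 without N2 and P1) and 0.855 for 28 p53 targets, 0.01 and 0.937 for 24 handling stress genes and -0.15 and 0.596 for 31 S phase genes. They were -0.03 (0.11 scaled to total counts) and 0.596 for 31 pan-macrophage genes, 0.04 and 0.965 for 10 mitochondrially encoded transcripts, 0.53 and 0.287 for 5 replication-dependent histone genes, 0.23 and 0.287 for 14 stromal and endothelial markers, 0.01 and 0.809 for 7 mast cell, basophil and eosinophil markers, 0.02 and 0.965 for 11 osteoclast markers and -0.10 (0.03 scaled to total counts) and 0.937 for 5 B and plasma cell markers. Without N2 and P1 the medians changed sign for the unfolded protein response (-0.04), M1-type (-0.03), handling stress (-0.16), mast cell (-0.11), osteoclast (-0.13), pan-macrophage (0.01) and B cell (0.25) lists. With the GC and length trend removed, the mitochondrially encoded transcripts passed (median 0.35, adjusted p = 0.000265), though not with an estimated correlation (0.753), and the medians changed sign for the MHC class I (-0.09), unfolded protein response (-0.13), growth factor (-0.10), glycolysis (-0.02), handling stress (-0.12), mast cell (-0.13), osteoclast (-0.09), inflammasome (0.10), sensor (0.06), pan-macrophage (0.05) and tumoricidal (0.01) lists. After that removal the median was 0.05 for the glucocorticoid, 0.07 for the oxidative phosphorylation and 0.08 for the metallothionein and iron list. It was 0.01 for the matrix list, 0.02 for the lipid uptake and MHC class II lists and, larger than before, 0.16 for the p53 list. In the main fit, camera's direction was lower against a positive median for the serotonin, unfolded protein response, growth factor, handling stress, mast cell and osteoclast lists, and higher against a negative median for the pan-macrophage and tumoricidal lists, and the means of the pan-macrophage, tumoricidal, sensor and B cell lists were positive against negative medians. Too few markers passed the count filter to test T and NK cells (4 of 23), erythroid cells and megakaryocytes (4 of 17) and lung epithelium (1 of 19). Gapdh, singled out after its values were seen, was at 6.52 ± 2.70 and 11.2 ± 4.11 CPM. Like the ribosomal protein genes it has many pseudogene copies.

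The rise of fold changes with GC content was set against 3 explanations. Length is argued against, since the partial Spearman correlation of fold change with length, given GC content, was 0.072. Recovery in library preparation or sequencing that varies with GC content between libraries may account for at least part, since libraries of the same group also differed along GC content, with a largest rho of 0.33, between N1 and N2, and absolute values of 0.05 to 0.20 for the other 5 pairs. In simulated counts where no gene changed but each library carried its measured trend, 12.5% of genes had an unadjusted p under 0.05, and 4.7% after the correction. Per simulation these were 1185 to 1277 and 454 to 486 genes, against 1690 and 961 in the data. The simulated trend includes the difference in slope between the groups, so this excess would arise whatever caused that difference. The medium cannot be told apart from such recovery, since the slopes separate the groups and the exact permutation p of 0.1 is the smallest the design gives.

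The higher ribosomal protein transcripts with HTR2C-positive medium remained past camera's threshold with the GC and length trend removed (adjusted p = 2.68e-14, median 0.31) where the median before was 0.36, which argues against that trend as the whole cause. With an estimated correlation the call was lost both before and after the removal (adjusted p = 0.798 and 0.753). Whether the list stands apart from other genes thus rests on the preset correlation and the degrees of freedom that go with it. With that preset no single library decided it, since the largest adjusted p over the 6 leave-one-out fits was 1.19e-06, with a positive median in each. An effect of the medium stays open, with an exact permutation p of 0.1 for the list means, the smallest possible, and so does a shift in RNA quality or in the handling of reads shared with pseudogenes, which was not tested.

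Library N2 correlated best with P1 of the other group (r = 0.980 over log2 CPM across genes, against 0.974 with N3). Removing the GC and length trend left r higher with P1 by 0.008, which argues against the trend as the cause. What N2 and P1 share stays open, a wrong label on either sample was not tested, and no biological explanation was tested.

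The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05, and counts of splits here include the real one. At least as many genes with an adjusted p under 0.05 came from 10 splits (0, highest other 0). For genes with an unadjusted p under 0.05 the real split gave 1690 and the highest other 1324, with 1 split as large, the real one itself. With the GC and length trend removed the real split gave 961 and the highest other 1326, that of N1, N3 and P2 against N2, P1 and P3, so the real grouping was then not the largest. For the fixed lists the values were 3 and 5, with 6 splits as large, and for the terms 13 and 27, with 4 splits as large, the real one included in each.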
